A study of Homo sapiens with 12 samples.

How the data were processed

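The deposited table gave, for 54127 human genes with an identifier, the normalized counts of the 12 libraries, packed as 1 value per library in 1 cell per group and run. Per the file headers the groups were V0, KPC1 and p50 of run 1 and V0 and KPC1 of run 2. The values of a cell carry no replicate number, so libraries are named a, b and c by position, and no library could be paired with one of another group or with a sample record. Means of the packed values matched the base means in the deposited table to within 0.00431 in run 1 and 0.00422 in run 2. Per the submitters' processing notes the tools were TopHat2 2.0.9, HTSeq 0.5.3p3, DESeq2 1.2.8, Bowtie2 2.2.2, Cufflinks 2.2.1 and Cuffnorm, with the builds GRCh37 and NCBIM37 and with no role or order given for each tool. Strand use and the handling of reads with several positions were not given in the sources used here. Reads mapped to mouse genes were not analysed here. The columns with p-values and adjusted p-values in the deposited table are those of the authors and were used only to set their calls beside the ones made here. A second annotation, GENCODE v29, served only to match symbols and gene types, and no coordinates were taken from it.

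The values were normalized counts, with 1 size factor per library of a run, where the design assumed counts as deposited. The fallback written in the design for normalized values was therefore used. This was limma-trend on log2 of the value + 1, with the adjusted p of Benjamini and Hochberg under 0.05. Dividing each library by its smallest step gave whole reads for 100% of the values, which served for depth and for an alternative with limma-voom. Genes with at least 10 normalized counts in at least 2 libraries of a run were tested. Run 1 was fitted with all 7 libraries, run 2 with 5, and both runs together with 10 libraries and run as a term, and the difference of the KPC1 effect between runs was the interaction of group and run. Residual degrees of freedom were 4 in run 1, 3 in run 2, 7 over both runs and 6 for the interaction. A p that misses the threshold does not show that there was no difference, and an effect that passed in 1 run or group only is shown to differ only where the interaction or the direct comparison passed. The comparisons, the threshold, the 27 gene lists and all alternatives but 1 were chosen before the data were examined, and scaling by trimmed means (TMM) was added afterwards. The filter written in the design was one for counts, and the filter on normalized counts given above took its place.

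Gene lists with at least 3 tested members, 24 of 27, were tested with camera of limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, the adjusted p being taken over the lists of a comparison. The lists were NF-kB targets and components, tumour suppressors, LIN28B with let-7 targets and oncofetal genes, cell cycle, hypoxia, angiogenesis, matrix, interferon, antigen presentation, apoptosis, unfolded protein response, immediate early and heat shock, proteasome, cholesterol, glial, ribosomal and mitochondrially encoded genes, and markers of endothelial cells, fibroblasts, muscle, macrophages, adipocytes, keratinocytes, neutrophils, lymphocytes and erythroid cells. Of 597 symbols 586 were matched. Camera asks whether the genes of a list move relative to all others. Fry of limma asks whether the genes of a list move on balance in 1 direction, or in its mixed form in either direction, and neither form compares them with other genes. Fry depends slightly on the order of the groups in the model, which was fixed as alphabetical.

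RNF123 and NFKB1 were named in every comparison. Further named genes were those past an adjusted p of 0.05, with a mean of at least 5 in the higher group and no overlap between the libraries of the groups, that had the 10 largest or 10 smallest log2 fold changes. From each list up to 2 members that rose and 2 that fell with the smallest adjusted p were named, and where none passed the 1 or 2 with the smallest p were given as values. Pseudogenes, clones and uncharacterized loci were left out of the largest changes, which was applied to clone names, symbols starting with LOC, LINC or KIAA, open reading frame symbols, small RNA families, pseudogene types, copies outside the main chromosomes and genes of the Y chromosome. Symbols with TMEM, FAM, CCDC or MIR and antisense symbols were kept.

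The filter and the test per gene were run on simulated counts with known changes, and the list tests were not. Changed genes were drawn only from those above a minimum mean count, and 1 spread per gene served for all groups. The shares found thus do not apply to low-count genes or to groups that differ in spread. Of the genes changed 1.5-fold, 2-fold and 4-fold, 38.8%, 58.2% and 93.9% were found for KPC1 against V0 in run 1, and 35.8%, 65.7% and 93.9% for p50 against V0. The corresponding shares were 22.4%, 52.2% and 92.4% for KPC1 against p50, 14.9%, 56.7% and 95.5% for KPC1 against V0 in run 2, 53.7%, 82.1% and 93.9% over both runs, and 14.9%, 50.7% and 87.9% for the interaction. Between 3 and 9 unchanged genes were called per comparison. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.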

Results

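RNA was sequenced from tumours that U87-MG cells, an established human glioblastoma line, had formed under the skin of nude mice 21 days after inoculation. The cells carried an empty vector (V0), a vector for KPC1, the ubiquitin ligase coded by RNF123, or a vector for p50, the NF-kB subunit that is part of the NFKB1 product. Run 1 gave 3 V0, 2 KPC1 and 2 p50 libraries, and run 2, an independent repeat, gave 3 V0 and 2 KPC1 libraries. Each V0 library came from 1 tumour, each KPC1 library from a pool of 3 tumours and each p50 library from a pool of 2 or 3. The spread between V0 libraries was thus a spread between tumours and the spread between KPC1 or p50 libraries a spread between pools. The libraries of a group are called a, b and c in the order of their values in the deposited table.

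The V0 libraries were deeper than the pools. In run 1 they held 22.2, 20.7 and 18.4 M (mega) reads counted on human genes, the KPC1 libraries 15.5 and 16.3 M and the p50 libraries 14.9 and 11.9 M. In run 2 the V0 libraries held 18.7, 26.8 and 21.6 M and the KPC1 libraries 17.1 and 18.0 M. Between 23355 and 27047 genes had a value above 0 in a library. The 10 most abundant genes took 4.62% to 5.31% of the reads in V0 and 7.66% to 9.62% in KPC1 and p50 libraries of run 1. In run 2 they took 5.23% to 6.03% in V0 and 6.49% to 6.57% in KPC1 libraries. Mitochondrially encoded genes took 1.66% to 2.40% in V0, 2.2% to 2.22% in KPC1 and 2.65% to 2.73% in p50 libraries of run 1. In run 2 they took 1.41% to 1.86% in V0 and 3.67% to 3.84% in KPC1 libraries. The first 2 principal components held 50.5% and 30.3% of the variance in run 1 and 77.6% and 13.1% in run 2.

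RNF123 (ENSG00000164068, chromosome 3, 49726932 to 49758962, GRCh37) was raised in every KPC1 library. Its normalized counts in run 1 were 616, 583 and 656 in V0, 13356 and 16560 in KPC1, and 721 and 614 in p50 tumours. In run 2, normalized separately, they were 674, 752 and 714 in V0 and 50126 and 48649 in KPC1 tumours. Relative to V0 it rose by 4.59 ± 0.12 on the log2 scale in run 1 (SE, limma adjusted p = 1.8e-06) and by 6.11 ± 0.08 in run 2 (adjusted p = 4.6e-06). In contrast, p50 tumours differed from V0 by 0.11 ± 0.12 (adjusted p = 0.50). NFKB1 (ENSG00000109320, chromosome 4, 103422486 to 103538459, GRCh37) stood at 3246 and 3322 normalized counts in p50 tumours against 1141, 895 and 1224 in V0 and 1083 and 949 in KPC1 tumours of run 1. It rose by 1.61 ± 0.14 in p50 tumours (adjusted p = 0.00011). In KPC1 tumours NFKB1 did not pass, with -0.09 ± 0.14 in run 1 (adjusted p = 0.68) and -0.08 ± 0.15 in run 2 (adjusted p = 0.72), where its counts were 1560, 1190 and 1129 in V0 and 1205 and 1218 in KPC1 tumours.

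**Figure D1:**
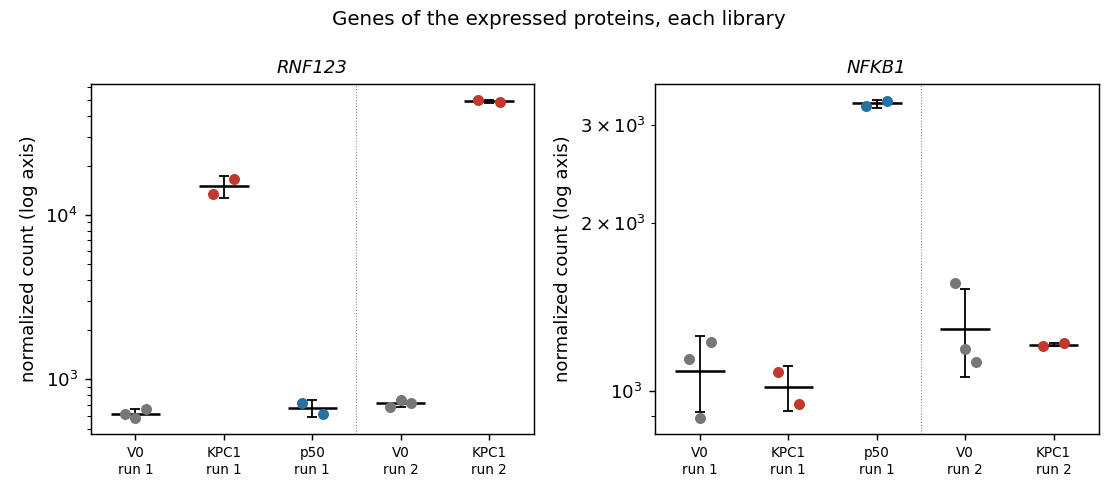
Normalized counts of RNF123 and NFKB1 on a log axis in the 12 libraries, by group and run; points are libraries, lines group means and bars SDs, and counts were normalized separately per run. RNF123 lies between 583 and 752 in V0 and p50 libraries and between 13356 and 50126 in KPC1 libraries, and NFKB1 is highest in the p50 libraries, at 3246 and 3322.

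The comparison of KPC1 with V0 tumours in run 1 asked which transcripts moved with a raised level of the ligase (2 pools against 3 tumours). NF-kB target genes fell. SOD2, which codes for the mitochondrial superoxide dismutase, fell by 2.10 ± 0.18 on the log2 scale (SE, adjusted p = 0.00027), from 20227 ± 4389 to 4643 ± 492 normalized counts (SD, n = 3 and 2). TNFAIP3, which codes for a feedback inhibitor of NF-kB signalling, fell by 1.4 ± 0.18 (adjusted p = 0.0013). The interleukin genes IL1RN and IL36RN, which code for receptor antagonists, fell too (-4.63 ± 0.47 and -4.14 ± 0.34, adjusted p = 0.00053 and 0.00022). VCAM1, an adhesion molecule gene on the same list, rose by 2.66 ± 0.41 (adjusted p = 0.0031). The NF-kB inhibitor gene NFKBIA fell by 0.87 ± 0.19 (adjusted p = 0.014), which no longer passed without KPC1 library a (adjusted p = 0.0736) or b (adjusted p = 0.135). Of 28 NF-kB target genes 18 fell, 2 rose and 8 did not pass, with 21 and 3 adjusted over the list alone (median -1.04, camera adjusted p = 4.6e-06, adjusted p = 0.336 with an estimated correlation). The list of 26 NF-kB pathway components shares NFKB2, RELB, NFKBIA and NFKBIE with the target list. Of the components 7 fell, RNF123 rose and 18 did not pass, also when adjusted over the list alone (median -0.19, camera adjusted p = 0.024, adjusted p = 0.375 with an estimated correlation). This call was lost without V0 library a (adjusted p = 0.0527) and with fry (adjusted p = 0.714).

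Proliferation and sterol genes fell with KPC1 in run 1. MKI67, the gene of a nuclear protein of cycling cells, fell by 0.90 ± 0.07 (adjusted p = 0.00022) and the transcription factor gene E2F1 by 0.68 ± 0.08 (adjusted p = 0.00094). FDFT1 and EBP, which code for enzymes of cholesterol synthesis, fell by 1.13 ± 0.08 and 1.13 ± 0.09 (adjusted p = 0.00016 and 0.00017). HMGA2, a chromatin protein gene repressed by let-7 microRNAs, fell by 0.97 ± 0.09 (adjusted p = 0.00039) and the cyclin gene CCND1 by 0.99 ± 0.11 (adjusted p = 0.00061). Of 36 cell cycle genes 26 fell and 10 did not pass, with 32 lower adjusted over the list alone (median -0.47, camera adjusted p = 2.9e-13, adjusted p = 0.268 with an estimated correlation). Of 23 cholesterol genes 19 fell and 4 did not pass, the same counts adjusted over the list alone (median -0.69, camera adjusted p = 2.5e-12, adjusted p = 0.268 with an estimated correlation). Among 39 ribosomal protein genes 18 fell and 21 did not pass, with 21 lower adjusted over the list alone (median -0.28, camera adjusted p = 2.3e-08, adjusted p = 0.336 with an estimated correlation). Among 33 proteasome subunits 7 fell and 26 did not pass, with 6 lower adjusted over the list alone (median -0.22, camera adjusted p = 2.4e-05, adjusted p = 0.345 with an estimated correlation). In the list of LIN28B, let-7 targets and oncofetal genes 7 of 14 fell, 1 rose and 6 did not pass, with 8 and 1 adjusted over the list alone (median -0.60, camera adjusted p = 0.00031, adjusted p = 0.268 with an estimated correlation).

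Hypoxia and glycolysis genes fell and genes of vessels and matrix rose in the same comparison. VEGFA, the vascular growth factor gene, fell by 1.46 ± 0.24 (adjusted p = 0.0040), which missed the threshold without KPC1 library a (-1.39, adjusted p = 0.0526). POSTN, which codes for the matrix protein periostin, rose by 2.87 ± 0.27 (adjusted p = 0.00036) to 56113 ± 2119 normalized counts from 8033 ± 2912. The connective tissue growth factor gene CTGF rose by 1.96 ± 0.09 (adjusted p = 2.4e-05). ANGPT1, a ligand of the endothelial receptor TEK, rose by 1.76 ± 0.13 (adjusted p = 0.00016). Of 32 hypoxia genes 14 fell, 1 rose and 17 did not pass, with 17 and 1 adjusted over the list alone (median -0.53, camera adjusted p = 3.9e-05, adjusted p = 0.496 with an estimated correlation). Of 37 matrix genes 22 rose, 1 fell and 14 did not pass, with 25 and 2 adjusted over the list alone (median 0.90, camera adjusted p = 3.3e-11, adjusted p = 0.268 with an estimated correlation). Among 26 angiogenesis genes 12 rose, 5 fell and 9 did not pass, with 13 and 5 adjusted over the list alone (median 0.44, camera adjusted p = 0.0083, adjusted p = 0.345 with an estimated correlation), a call lost without V0 library a (adjusted p = 0.160).

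Markers of host-type tissue moved with KPC1 in run 1. Of 17 fibroblast and pericyte markers 13 rose and 4 did not pass, with 14 higher adjusted over the list alone (median 1.85, camera adjusted p = 1.4e-10, adjusted p = 0.268 with an estimated correlation), and the matrix list holds 6 of these genes. PDGFRB, a pericyte receptor gene, rose by 1.91 ± 0.14 (adjusted p = 0.00017). Of 14 endothelial markers 7 rose and 7 did not pass, with 8 higher and 1 lower adjusted over the list alone (median 0.84, camera adjusted p = 0.0018, adjusted p = 0.268 with an estimated correlation), and TIE1, an endothelial receptor gene, rose by 1.43 ± 0.19 (adjusted p = 0.0016). Among 11 skeletal muscle markers 2 rose and 9 did not pass, with none passing when adjusted over the list alone (median 2.76, camera adjusted p = 0.0059, adjusted p = 0.496 with an estimated correlation). Among 5 keratinocyte markers DSP, a desmosome gene, rose by 5.08 ± 0.50 (adjusted p = 0.00045) and 4 did not pass, with 4 higher adjusted over the list alone (median 1.4, camera adjusted p = 0.031, adjusted p = 0.268 with an estimated correlation), a call lost without KPC1 library a (median 0.99, adjusted p = 0.273) or b (median 0.76, adjusted p = 0.338). Reads of mouse transcripts on human genes could not be told from human reads.

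Tumour suppressor, interferon and unfolded protein genes also moved with KPC1 in run 1. DAB2IP, which codes for a Ras GTPase-activating protein, rose by 1.74 ± 0.17 (adjusted p = 0.00045) and TXNIP, a thioredoxin inhibitor gene, by 0.96 ± 0.12 (adjusted p = 0.0011). Of 32 tumour suppressor genes 9 rose, 3 fell and 20 did not pass, with 10 and 3 adjusted over the list alone (median 0.18, camera adjusted p = 0.029, adjusted p = 0.375 with an estimated correlation), which was lost without V0 library b (adjusted p = 0.0814). Of 31 interferon response genes 11 rose, 4 fell and 16 did not pass, with 15 and 5 adjusted over the list alone (median 0.38, camera adjusted p = 0.024, adjusted p = 0.375 with an estimated correlation), which was lost without V0 library a (adjusted p = 0.0723). Within that list OAS2 rose by 1.93 ± 0.22 (adjusted p = 0.00083) and CMPK2, a mitochondrial nucleotide kinase gene, fell by 5.10 ± 0.23 (adjusted p = 2.4e-05). Of 23 unfolded protein response genes 6 rose, 2 fell and 15 did not pass, with 10 and 2 adjusted over the list alone (median 0.24, camera adjusted p = 0.043, adjusted p = 0.375 with an estimated correlation). That call was lost without V0 library a (adjusted p = 0.115), KPC1 library b (adjusted p = 0.0740), p50 library a (adjusted p = 0.0536) or p50 library b (adjusted p = 0.0541). For the 12 mitochondrially encoded genes, none of which passed, the median was 0.18 (camera adjusted p = 0.170), and the list passed without V0 library a (median 0.30, adjusted p = 0.00673). The 10 macrophage markers had a median of 0.49 with 2 higher and 1 lower (camera adjusted p = 0.257) and passed without V0 library c (median 0.94, adjusted p = 0.037).

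The remaining lists did not pass with KPC1 in run 1. Antigen presentation genes had 2 of 20 lower (median 0.21, camera adjusted p = 0.204), and apoptosis regulators had 4 higher and 2 lower of 24 (median 0.10, camera adjusted p = 0.170), with the trail ligand gene TNFSF10 up by 2.29 ± 0.22 (adjusted p = 0.00044). Immediate early and heat shock genes had 4 higher and 3 lower of 24 (camera adjusted p = 0.538), and their median of -0.13 and mean of 0.08 differed in sign. Glial genes had 2 higher and 3 lower of 17 (median 0.06, camera adjusted p = 0.879) and adipocyte markers 2 higher of 5 (median 1.04, camera adjusted p = 0.234). Adjusted over the list alone, the same counts of these lists passed except for apoptosis regulators, with 5 higher and 3 lower. Neutrophil, lymphocyte and erythroid markers had fewer than 3 tested members and were not tested as lists.

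Among single genes, the largest rises with KPC1 in run 1 were in SPINT2 (8.12 ± 0.69, adjusted p = 0.00025), CD96 (7.93 ± 0.64, adjusted p = 0.00022), FOXQ1 (7.55 ± 0.50, adjusted p = 0.00011) and KRT19, a simple epithelial keratin gene (6.65 ± 0.58, adjusted p = 0.00029). TMEM132D was listed at 0 in every V0 library and reached a mean of 84.5 normalized counts in KPC1. IL1B and CCL20 fell by 4.93 ± 1.14 and 4.06 ± 0.89 (adjusted p = 0.017 and 0.014), and neither passed with limma-voom or without KPC1 library a or b. Of 17794 genes tested 2292 rose and 1866 fell, 4158 in all, and 6568 had an unadjusted p under 0.05. Leaving out KPC1 library a or b brought the number to 1136 or 1011, with the lone library taken to vary like the other groups. At a minimum of 2-fold 1203 rose and 353 fell. The authors' deposited table had 5641 of 18905 genes past the threshold for this comparison, 4111 of the 4158 among them in the same direction, with 0 in the opposite one.

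**Figure D2:**
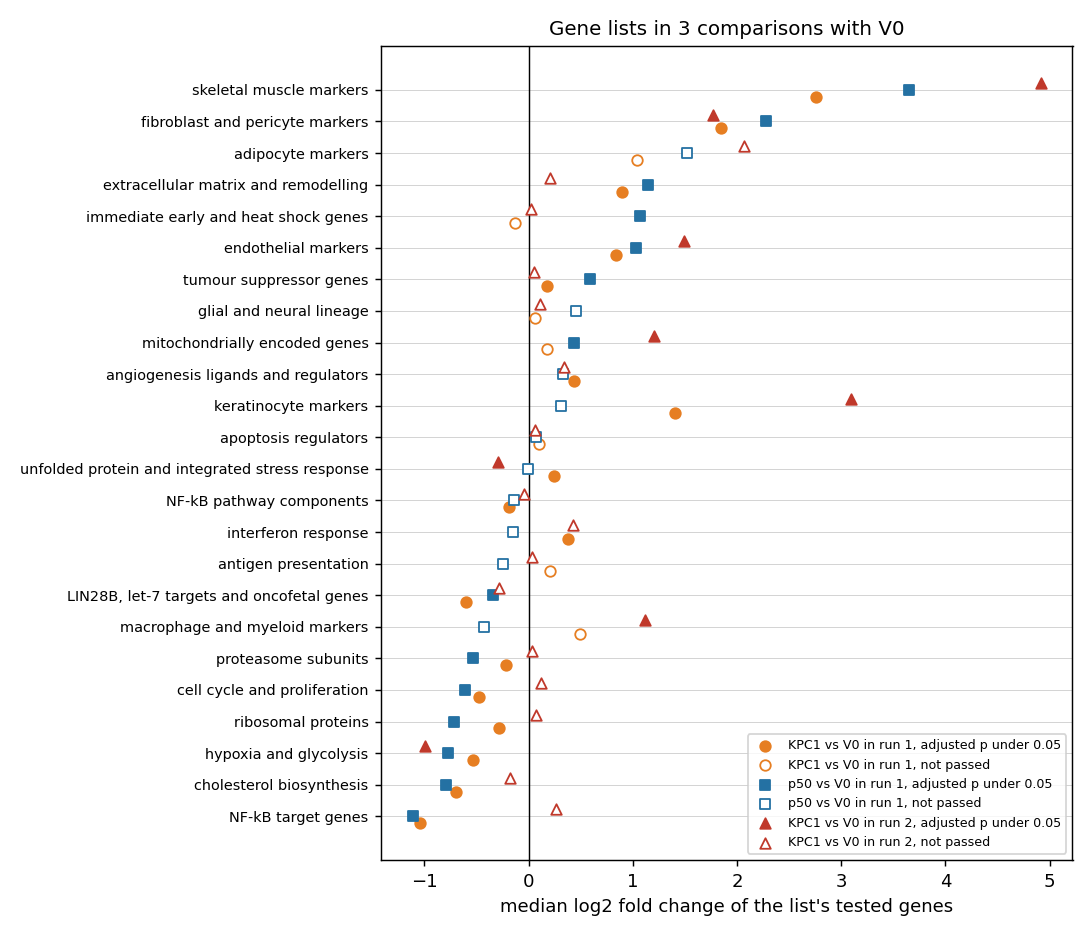
Median log2 fold change of each gene list (horizontal axis, log2 units) in KPC1 against V0 in run 1 (circles), p50 against V0 in run 1 (squares) and KPC1 against V0 in run 2 (triangles); filled symbols passed camera at a preset correlation, and none passed with an estimated one. Hypoxia genes lie at -0.53, -0.78 and -1.0 and fibroblast markers at 1.85, 2.27 and 1.77, while NF-kB targets lie at -1.04 and -1.11 in run 1 and at 0.26 in run 2.

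The comparison of p50 with V0 tumours in run 1 asked which transcripts moved with the NF-kB subunit itself (2 pools against 3 tumours). SOD2 fell by 3.5 ± 0.18 (SE, adjusted p = 2.0e-05) to 1765 ± 198 normalized counts (SD, n = 2). IL1RN, IL36RN and IL36B fell as well (-7.94 ± 0.47, -7.52 ± 0.34 and -7.34 ± 0.25, adjusted p = 3.6e-05, 1.3e-05 and 4.1e-06). Early response transcription factor genes rose, with FOSB up by 6.73 ± 0.29 (adjusted p = 1.1e-05), EGR3 by 5.70 ± 0.23 (adjusted p = 9.3e-06), NR4A1 by 5.11 ± 0.17 (adjusted p = 4.1e-06) and EGR1 by 4.95 ± 0.31 (adjusted p = 3.7e-05). EGR1 stood at 23031 ± 122 normalized counts in p50 against 794 ± 315 in V0 tumours (SD, n = 2 and 3). Of 24 immediate early and heat shock genes 16 rose, 1 fell and 7 did not pass, also when adjusted over the list alone (median 1.07, camera adjusted p = 8.7e-08, adjusted p = 0.257 with an estimated correlation). Of 28 NF-kB target genes 18 fell, 2 rose and 8 did not pass, with 19 and 2 adjusted over the list alone (median -1.11, camera adjusted p = 3.6e-05, adjusted p = 0.319 with an estimated correlation). The 26 NF-kB components had 6 lower and 2 higher, NFKB1 and TRAF6, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.233).

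Ribosomal, cell cycle and proteasome genes fell with p50. The ribosomal protein genes RPL8 and RPS16 fell by 1.14 ± 0.08 and 1.06 ± 0.08 (adjusted p = 7.0e-05 and 7.5e-05), AURKB, a mitotic kinase gene, by 1.27 ± 0.11 (adjusted p = 0.00014). HMGA2 fell by 1.67 ± 0.09 (adjusted p = 2.7e-05). KLF6, a zinc finger transcription factor gene, rose by 1.46 ± 0.09 (adjusted p = 3.7e-05) and TXNIP by 1.51 ± 0.12 (adjusted p = 8.1e-05). Of 39 ribosomal protein genes 38 fell and 1 did not pass, also when adjusted over the list alone (median -0.72, camera adjusted p = 2.7e-16, adjusted p = 0.257 with an estimated correlation). Of 36 cell cycle genes 32 fell and 4 did not pass, also adjusted over the list alone (median -0.61, camera adjusted p = 2.2e-12, adjusted p = 0.257 with an estimated correlation). Of 33 proteasome subunits 27 fell and 6 did not pass, with 28 lower adjusted over the list alone (median -0.53, camera adjusted p = 1.5e-09, adjusted p = 0.257 with an estimated correlation). Of 23 cholesterol genes 21 fell and 2 did not pass, also adjusted over the list alone (median -0.79, camera adjusted p = 1.5e-09, adjusted p = 0.257 with an estimated correlation). Of 32 tumour suppressor genes 21 rose, 1 fell and 10 did not pass, also adjusted over the list alone (median 0.59, camera adjusted p = 1.0e-06, adjusted p = 0.257 with an estimated correlation). In the LIN28B and let-7 list 7 of 14 fell, 2 rose and 5 did not pass, also adjusted over the list alone (median -0.34, camera adjusted p = 0.032, adjusted p = 0.257 with an estimated correlation).

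Hypoxia, matrix and host-type genes moved with p50 as well. ENO1, a glycolytic enzyme gene, fell by 0.83 ± 0.10 (adjusted p = 0.00051). VEGFA fell by 1.02 ± 0.24 (adjusted p = 0.0097), which missed the threshold without p50 library a (-1.05, adjusted p = 0.0613) or b (-0.99, adjusted p = 0.0751). POSTN rose by 3.40 ± 0.27 (adjusted p = 8.7e-05), CTGF by 3.48 ± 0.09 (adjusted p = 1.6e-06) and the endothelial marker gene CD34 by 2.47 ± 0.26 (adjusted p = 0.00031). Of 32 hypoxia genes 17 fell, 2 rose and 13 did not pass, with 17 and 3 adjusted over the list alone (median -0.78, camera adjusted p = 0.00099, adjusted p = 0.640 with an estimated correlation). Of 37 matrix genes 24 rose, 6 fell and 7 did not pass, also adjusted over the list alone (median 1.15, camera adjusted p = 4.3e-06, adjusted p = 0.327 with an estimated correlation). Fibroblast markers rose in 14 of 17 with 1 lower, also adjusted over the list alone (median 2.27, camera adjusted p = 7.8e-08, adjusted p = 0.257 with an estimated correlation). Endothelial markers rose in 7 of 14, also adjusted over the list alone (median 1.03, camera adjusted p = 0.020, adjusted p = 0.257 with an estimated correlation). Skeletal muscle markers rose in 6 of 11, and in 11 adjusted over the list alone (median 3.65, camera adjusted p = 0.0030, adjusted p = 0.554 with an estimated correlation). Mitochondrially encoded genes rose in 5 of 12, and in 7 adjusted over the list alone (median 0.43, camera adjusted p = 0.0038, adjusted p = 0.554 with an estimated correlation), and MT-ND6 rose by 0.81 ± 0.14 (adjusted p = 0.0026).

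The other 10 lists did not pass with p50, with medians from -0.42 in macrophage markers to 1.52 in adipocyte markers. Unfolded protein response genes went both ways, with 5 higher and 8 lower of 23, and their median lay below 0 and their mean above it, the median changing sign with the scaling. Angiogenesis genes had a median of 0.33 with 11 higher and 6 lower of 26 (camera adjusted p = 0.0602), and passed without V0 library c (adjusted p = 0.0402) or p50 library b (adjusted p = 0.0454) and with TMM scaling (adjusted p = 0.0465). Antigen presentation genes had a median of -0.25 with 5 of 20 lower (camera adjusted p = 0.0602) and passed without V0 library a (median -0.50, adjusted p = 7.87e-05) and with limma-voom (adjusted p = 0.0496). Macrophage markers had 4 lower and 1 higher of 10 (camera adjusted p = 0.164) and passed without V0 library b (median -0.80, adjusted p = 0.0373). Adipocyte markers had 2 higher of 5 (camera adjusted p = 0.0602) and passed without KPC1 library a (adjusted p = 0.0485) or b (adjusted p = 0.0476) or p50 library b (median 3.18, adjusted p = 0.0479) and with TMM scaling (adjusted p = 0.0483). MMP12, a macrophage elastase gene, had the largest rise of a gene in this comparison (7.68 ± 0.49, adjusted p = 4.1e-05). Of 17794 genes tested 3651 rose and 3900 fell, 7551 in all, which came to 3910 without p50 library a and 3715 without b. At least 2-fold changes were found in 1581 higher and 949 lower genes. The authors' deposited table had 8386 genes past the threshold, 7394 of the 7551 among them in the same direction and 0 in the opposite one.

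The comparison of KPC1 with p50 tumours in run 1 asked where the ligase and the subunit differed (2 pools of each). Early response genes were lower with KPC1, NR4A1 by a log2 fold change of -5.25 ± 0.18 (adjusted p = 1.1e-05), EGR3 by -5.52 ± 0.25 (adjusted p = 3.5e-05) and EGR1 by -4.58 ± 0.34 (adjusted p = 0.00023). SOD2 was higher with KPC1 by 1.4 ± 0.20 (adjusted p = 0.0033), CCL2, a monocyte chemokine gene, by 2.14 ± 0.14 (adjusted p = 0.00015), and the glutamate transporter gene SLC1A3 by 2.34 ± 0.12 (adjusted p = 5.3e-05). CTGF was lower (-1.52 ± 0.10, adjusted p = 0.00012). MAGEC1, FOXQ1 and MRS2 were listed at 0 in both p50 libraries and had means of 427, 237 and 106 normalized counts in KPC1. MAGEA6 was also listed at 0 with p50. Reads of MAGEA6 and its near-identical copy MAGEA3 may be split between them, which leaves both uncertain. The antisense gene UBE3A-AS1 is uncertain too, since strand use was not given in the sources used here. Of 17794 genes tested 2006 were higher and 1457 lower with KPC1, 3463 in all. That number was 579 and 890 without KPC1 libraries a and b, 943 and 783 without p50 libraries a and b, 5937 without V0 library a, and 7791 when only the groups compared were fitted. The spread used for the 3463 was shared with the single V0 tumours, whose pairs differed with SDs of 0.449 to 0.561 on the log2 scale, against 0.328 and 0.283 for the KPC1 and p50 pools.

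Between KPC1 and p50 9 of 24 lists passed, immediate early and heat shock genes with the largest median. Of 24 immediate early genes 17 were lower and 7 did not pass, with 17 lower and 1 higher adjusted over the list alone (median -1.36, camera adjusted p = 1.65e-13, adjusted p = 0.324 with an estimated correlation). Of 39 ribosomal protein genes 29 were higher and 10 did not pass, with 32 higher adjusted over the list alone (median 0.43, camera adjusted p = 1.45e-12, adjusted p = 0.539 with an estimated correlation). Proteasome subunits were higher in 9 of 33, and in 15 adjusted over the list alone (median 0.27, camera adjusted p = 2.25e-05, adjusted p = 0.732 with an estimated correlation). Tumour suppressor genes were lower in 10 of 32, and in 13 adjusted over the list alone (median -0.32, camera adjusted p = 0.00018, adjusted p = 0.539 with an estimated correlation). Interferon genes were higher in 15 of 31, with 16 higher and 3 lower adjusted over the list alone (median 0.63, camera adjusted p = 0.00033, adjusted p = 0.590 with an estimated correlation). Antigen presentation genes were higher in 4 of 20, and in 7 adjusted over the list alone (median 0.47, camera adjusted p = 0.0021, adjusted p = 0.801 with an estimated correlation). Macrophage markers were higher in 5 of 10, also adjusted over the list alone (median 0.92, camera adjusted p = 0.0053, adjusted p = 0.741 with an estimated correlation). Cell cycle genes were higher in 4 and lower in 1 of 36, with 1 higher adjusted over the list alone (median 0.20, camera adjusted p = 0.014, adjusted p = 0.845 with an estimated correlation). Mitochondrially encoded genes were lower in 2 of 12, also adjusted over the list alone (median -0.23, camera adjusted p = 0.025, adjusted p = 0.864 with an estimated correlation).

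NF-kB targets did not pass between KPC1 and p50 (6 higher and 1 lower of 28, median 0.15, camera adjusted p = 0.284). Cholesterol genes had 1 higher and 3 lower of 23 (median 0.12, camera adjusted p = 0.460) and passed without KPC1 library b (median 0.27, adjusted p = 0.0278). Unfolded protein genes had 8 higher and 2 lower of 23 (median 0.09, camera adjusted p = 0.105) and passed without KPC1 library a (adjusted p = 0.0384). Median and mean differed in sign for NF-kB components, whose median flips with the scaling, and for angiogenesis, matrix and endothelial genes, and the test differed in sign from both for apoptosis regulators.

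KPC1 and p50 shared many of their changes from V0 in run 1. Both were pools and V0 libraries single tumours, so sharing from the proteins cannot be told from sharing through pooling. SOD2 and HMGA2 fell and POSTN and CTGF rose in both. Genes called in both comparisons were higher in both in 1506 cases, lower in both in 1284 and opposite in 152, against 470, 409 and 885 for independent lists of those sizes. Across 17794 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.530 and a Spearman rho of 0.580, and 72.8% had the same sign. Simulated data without effects, with all 7 libraries redrawn and V0 shared, gave a mean r of 0.398 (0.356 to 0.438 in 100 draws) and 63.1% with the same sign. The 0 shared calls in them follow from the construction. The simulation used 1 spread per gene for all groups, but V0 pairs differed with SDs of 0.449 to 0.561 and KPC1 and p50 pairs with 0.328 and 0.283. A wider V0 spread raises r without effects, so r and the share of equal signs do not show sharing. The covariance was 0.413 against a simulated 0.0378, a difference of 0.375. With different V0 libraries for each comparison the covariance lay between 0.327 and 0.408 and r between 0.358 and 0.485, where the simulated r, made with shared controls, does not apply. Since 3 control libraries cannot be split with 2 for each comparison, part of the excess may come from the shared controls. The covariance of 0.327 to 0.408 without shared V0 libraries argues against them as its only source. The simulated covariance rests on the same 1 spread per gene. Without V0 library c r was 0.573 and without KPC1 library a 0.612.

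**Figure D3:**
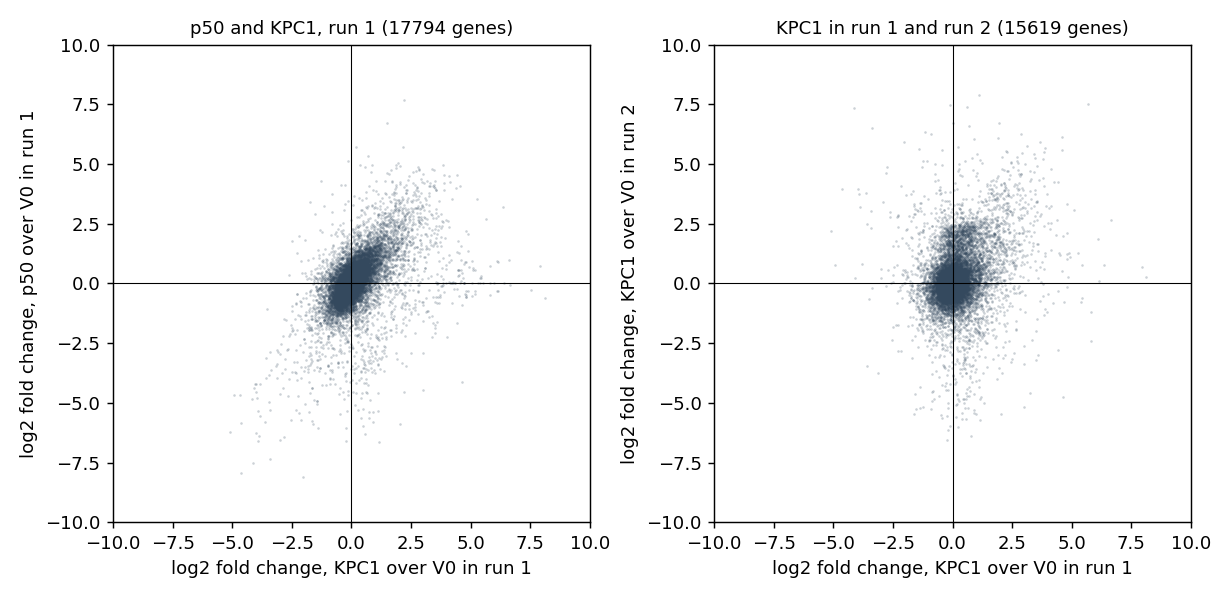
Log2 fold change of KPC1 against V0 in run 1 (horizontal axis) against p50 over V0 in run 1 (left, 17794 genes) and against KPC1 over V0 in run 2 (right, 15619 genes); points are genes. The correlation across genes was 0.530 on the left, where the V0 libraries are shared, and 0.270 on the right, where they are not.

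The comparison of KPC1 with V0 tumours in run 2 asked the same question in an independent experiment (2 pools against 3 tumours). Hypoxia genes fell. VEGFA fell by 2.67 ± 0.14 (SE, adjusted p = 0.00035), from 14284 ± 2285 to 2230 ± 86.2 normalized counts (SD, n = 3 and 2). ANGPTL4, a lipase inhibitor gene induced by hypoxia, fell by 1.89 ± 0.16 (adjusted p = 0.0011). LIN28B, which codes for a repressor of let-7 microRNAs, fell by 2.35 ± 0.32 (adjusted p = 0.0039). TLR4, a receptor gene upstream of NF-kB, fell by 5.97 ± 0.20 (adjusted p = 0.00016). It also varied between the V0 tumours of run 1, at 49.0, 268 and 162 normalized counts. Of the NF-kB targets ICAM1 fell by 3.01 ± 0.30 and LIF by 3.06 ± 0.32 (adjusted p = 0.0016 and 0.0018), while the chemokine gene CCL5 rose by 3.02 ± 0.25 (adjusted p = 0.00097). MT-ND1, a mitochondrially encoded subunit of complex I, rose by 1.69 ± 0.12 (adjusted p = 0.00067). Of 32 hypoxia genes 25 fell and 7 did not pass, with 26 lower adjusted over the list alone (median -1.0, camera adjusted p = 4.8e-10, adjusted p = 0.633 with an estimated correlation). All 12 mitochondrially encoded genes tested rose, also adjusted over the list alone (median 1.21, camera adjusted p = 7.1e-08, adjusted p = 0.633 with an estimated correlation). Unfolded protein genes fell in 8 and rose in 1 of 23, with 10 and 1 adjusted over the list alone (median -0.29, camera adjusted p = 0.016, adjusted p = 0.705 with an estimated correlation).

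Host-type markers rose with KPC1 in run 2. The smooth muscle actin gene ACTA2 rose by 2.69 ± 0.14 (adjusted p = 0.00035), CD34 by 2.51 ± 0.18 (adjusted p = 0.00071), the lysozyme gene LYZ by 2.49 ± 0.12 (adjusted p = 0.00031) and KRT14, a basal keratinocyte gene, by 6.63 ± 0.38 (adjusted p = 0.00041). Of 18 fibroblast markers 13 rose, 1 fell and 4 did not pass, also adjusted over the list alone (median 1.77, camera adjusted p = 8.8e-05, adjusted p = 0.633 with an estimated correlation). Skeletal muscle markers rose in 7 of 11, and in 11 adjusted over the list alone (median 4.92, camera adjusted p = 0.0020, adjusted p = 0.706 with an estimated correlation). Macrophage markers rose in 7 of 11, also adjusted over the list alone (median 1.12, camera adjusted p = 0.0066, adjusted p = 0.633 with an estimated correlation). Endothelial markers rose in 8 and fell in 2 of 13, also adjusted over the list alone (median 1.49, camera adjusted p = 0.016, adjusted p = 0.633 with an estimated correlation). Keratinocyte markers rose in 4 of 7, also adjusted over the list alone (median 3.09, camera adjusted p = 0.016, adjusted p = 0.633 with an estimated correlation), a call lost without KPC1 library a (median 0.94, adjusted p = 0.139) or b (median 0.89, adjusted p = 0.167).

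NF-kB targets did not pass in run 2, with 6 higher and 4 lower of 26 (median 0.26, mean -0.05, camera adjusted p = 0.823). Cell cycle genes had 5 higher and 3 lower of 36 (median 0.12, camera adjusted p = 0.466) and passed without V0 library a (adjusted p = 0.0482). Cholesterol genes had 1 higher and 2 lower of 23 (median -0.17, camera adjusted p = 0.480) and passed without V0 library b (median -0.26, adjusted p = 0.0374). Interferon genes had 10 higher and 4 lower of 31 (median 0.42, camera adjusted p = 0.0874) and passed without V0 library c (adjusted p = 0.02). Matrix genes had 9 higher and 3 lower of 36 (median 0.21, camera adjusted p = 0.241). The LIN28B and let-7 list had 2 higher and 6 lower of 15 (median -0.28, camera adjusted p = 0.168) and passed with fry (adjusted p = 0.0498). Fry also called NF-kB components, a list that holds RNF123, and glial genes higher (fry adjusted p = 0.0146 for each). Median and mean also differed in sign for NF-kB components, and the test pointed down where median and mean were above 0 for immediate early and glial genes.

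Single genes with large changes in run 2 included CRYBA4, a lens crystallin gene (7.5 ± 0.27, adjusted p = 0.00016), and IL13RA2, a decoy receptor gene for interleukin 13 (7.47 ± 0.26, adjusted p = 0.00016), both higher with KPC1, and E2F7, an atypical E2F repressor gene (-6.39 ± 0.37, adjusted p = 0.00041). IL36RN, lower with KPC1 in run 1, was higher by 7.33 ± 0.84 (adjusted p = 0.0023). The hair keratin genes KRT25 and KRT72 were listed at 0 in every V0 library and had means of 205 and 104.8 normalized counts with KPC1. Reads of mouse skin on these genes could not be told from human reads. SSX1 was lower (-6.55 ± 0.53, adjusted p = 0.00091), though members of its gene family may share reads. Of 17271 genes tested 3098 rose and 2382 fell, 5480 in all, which came to 1115 without KPC1 library a and 1110 without b. Changes of at least 2-fold were found in 1953 higher and 894 lower genes. The authors' deposited table had 6965 of 21516 genes past the threshold, 5395 of the 5480 among them in the same direction and 0 in the opposite one.

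Over both runs, with run as a term in the model, the comparison asked for the average change with KPC1, which need not hold in each run (4 pools against 6 tumours). VEGFA fell by 2.06 ± 0.26 (SE, adjusted p = 0.00095) and the carbonic anhydrase gene CA9 by 3.52 ± 0.64 (adjusted p = 0.0055). LIN28B fell by 2.02 ± 0.27 (adjusted p = 0.0012) and HMGA2 by 0.96 ± 0.11 (adjusted p = 0.00082). SULF1, which codes for a heparan sulfate sulfatase, rose by 4.46 ± 0.29 (adjusted p = 7.1e-05), and POSTN by 2.88 ± 0.28 (adjusted p = 0.00028). ANGPT1 rose by 1.73 ± 0.15 (adjusted p = 0.0002) and TNFSF10 by 2.62 ± 0.22 (adjusted p = 0.0002). IL6 fell by 2.06 ± 0.51 (adjusted p = 0.020), which missed the threshold without KPC1 library b of run 1 (-1.98, adjusted p = 0.0526) or of run 2 (-2.09, adjusted p = 0.0550) and with limma-voom (-2.04, adjusted p = 0.0939). Of 15297 genes tested 2062 rose and 1512 fell, 3574 in all, with 1700 and 1672 without KPC1 library a or b of run 2. At least 2-fold changes were found in 1080 higher and 176 lower genes.

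**Figure D4:**
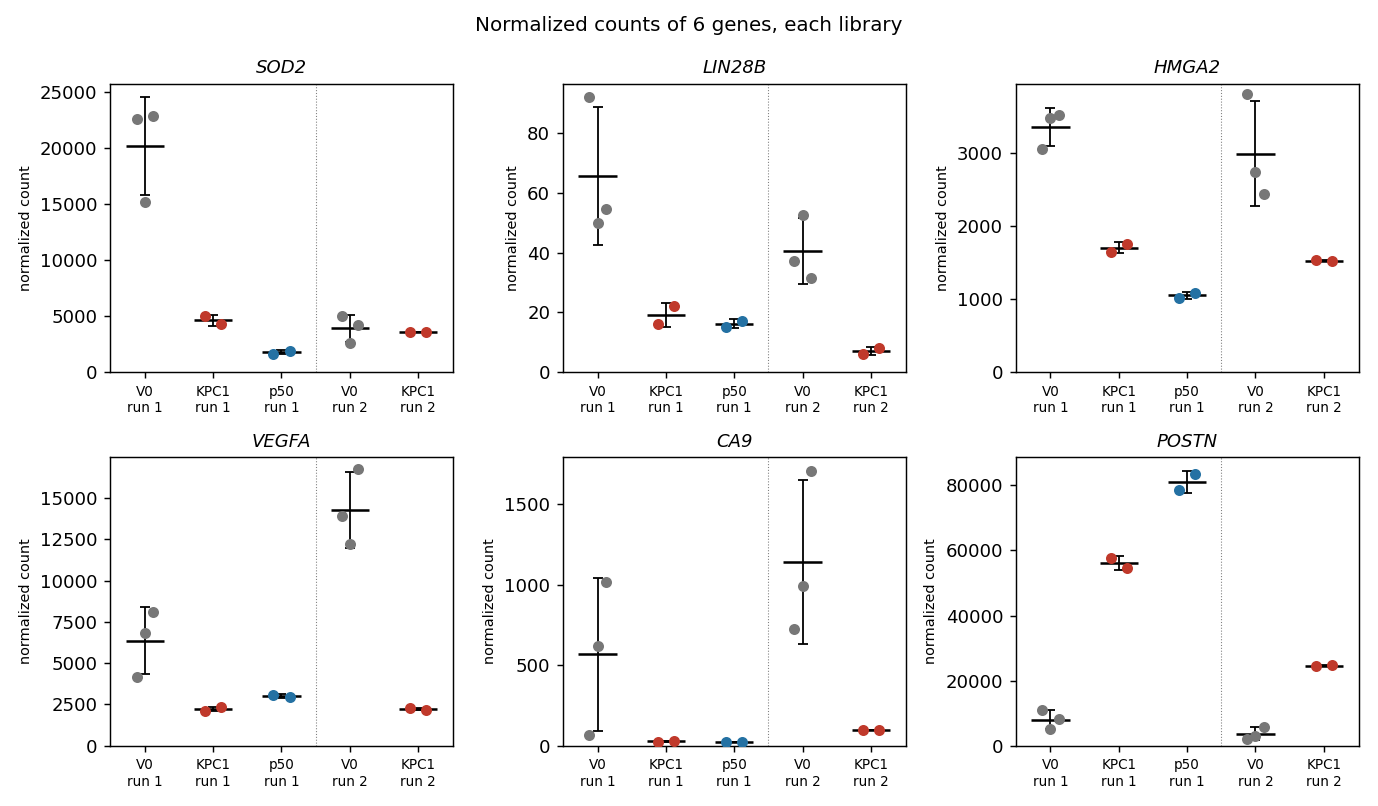
Normalized counts of SOD2, LIN28B, HMGA2, VEGFA, CA9 and POSTN by group and run, normalized separately per run; points are libraries and lines and bars are means and SDs. VEGFA has means of 6367, 2233 and 3017 in V0, KPC1 and p50 of run 1 and 14284 and 2230 in V0 and KPC1 of run 2, and SOD2 has 20227 in V0 of run 1 against 3921 in V0 of run 2.

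Over both runs 18 of 32 hypoxia genes fell and 14 did not pass, with 25 lower and 1 higher adjusted over the list alone (median -0.73, camera adjusted p = 6.25e-10, adjusted p = 0.445 with an estimated correlation). Cholesterol genes fell in 11 of 23, also adjusted over the list alone (median -0.36, camera adjusted p = 9.7e-06, adjusted p = 0.445 with an estimated correlation). Cell cycle genes fell in 10 of 36, also adjusted over the list alone (median -0.18, camera adjusted p = 0.00051, adjusted p = 0.540 with an estimated correlation). Ribosomal protein genes fell in 10 of 39, and in 11 adjusted over the list alone (median -0.10, camera adjusted p = 0.00115, adjusted p = 0.534 with an estimated correlation). In the LIN28B and let-7 list 6 of 14 fell, with 8 lower and 1 higher adjusted over the list alone (median -0.53, camera adjusted p = 0.0023, adjusted p = 0.137 with an estimated correlation). NF-kB targets fell in 6 and rose in 3 of 26, with 8 and 3 adjusted over the list alone (median -0.53, camera adjusted p = 0.030, adjusted p = 0.534 with an estimated correlation). That call was lost without V0 library a (adjusted p = 0.0563) or c (adjusted p = 0.122) or KPC1 library a (adjusted p = 0.098) or b (adjusted p = 0.165) of run 1. Proteasome subunits fell in 5 of 33, and in 1 adjusted over the list alone (median -0.14, camera adjusted p = 0.017, adjusted p = 0.595 with an estimated correlation), which was lost without V0 library a (adjusted p = 0.0745) or KPC1 library a (adjusted p = 0.0855) or b (median -0.06, adjusted p = 0.137) of run 1. The medians of NF-kB target, cell cycle, ribosomal and proteasome genes lay below 0 in run 1 but at 0.26, 0.12, 0.07 and 0.04 in run 2, so the average does not stand for run 2, and fry lost the calls (adjusted p = 0.230, 0.129, 0.0862 and 0.213).

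Matrix genes rose over both runs in 13 of 36, and in 15 adjusted over the list alone (median 0.49, camera adjusted p = 2.26e-05, adjusted p = 0.445 with an estimated correlation), though the list did not pass in run 2 alone. Fibroblast markers rose in 12 of 17, also adjusted over the list alone (median 1.85, camera adjusted p = 1.6e-08, adjusted p = 0.168 with an estimated correlation). Skeletal muscle markers rose in 6 of 11, and in 11 adjusted over the list alone (median 3.90, camera adjusted p = 0.00025, adjusted p = 0.445 with an estimated correlation). Endothelial markers rose in 5 of 12, and in 6 adjusted over the list alone (median 0.93, camera adjusted p = 0.0017, adjusted p = 0.137 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 12, and in 12 adjusted over the list alone (median 0.71, camera adjusted p = 0.000125, adjusted p = 0.445 with an estimated correlation). Interferon genes rose in 9 of 31, also adjusted over the list alone (median 0.25, camera adjusted p = 0.012, adjusted p = 0.445 with an estimated correlation). Keratinocyte markers rose in 2 of 5, and in 3 adjusted over the list alone (median 0.89, camera adjusted p = 0.029, adjusted p = 0.255 with an estimated correlation), a call lost without V0 library a (adjusted p = 0.0563) or KPC1 library a (median 0.31, adjusted p = 0.572) or b (median 0.26, adjusted p = 0.598) of run 1. Macrophage markers rose in 5 and fell in 1 of 10, with 6 and 1 adjusted over the list alone (median 0.87, camera adjusted p = 0.043, adjusted p = 0.489 with an estimated correlation), a call lost without V0 library a (adjusted p = 0.066) or b (adjusted p = 0.0737) of run 1 or V0 library b (adjusted p = 0.0753) or c (adjusted p = 0.0754) of run 2.

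Angiogenesis genes did not pass over both runs, with 7 higher and 2 lower of 25 (median 0.33, camera adjusted p = 0.0535), and passed without V0 library c of run 1 (adjusted p = 0.0441) or V0 library a (adjusted p = 0.035) or c (adjusted p = 0.033) of run 2, and also with upper quartile scaling (adjusted p = 0.0432), TMM scaling (adjusted p = 0.0437) and limma-voom (adjusted p = 0.0321). Tumour suppressor genes had 6 higher and 1 lower of 31 (median 0.14, camera adjusted p = 0.0833) and passed without V0 library c (adjusted p = 0.0418) or KPC1 library a (adjusted p = 0.035) or b (adjusted p = 0.0439) of run 2. The other lists did not pass, and median and mean differed in sign for NF-kB components, immediate early and glial genes.

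The 2 runs shared part of their KPC1 changes. VEGFA, CA9, LIN28B and HMGA2 were lower and POSTN, COL1A1 and TNFSF10 higher in each run and with p50. Of 15619 genes tested in both runs 754 rose in both, 302 fell in both and 340 went opposite ways, against 400, 242 and 623 for independent lists of those sizes. The log2 fold changes correlated across genes with a Pearson r of 0.270 and a Spearman rho of 0.235, with no control library shared, and 57.9% had the same sign. In all 3 comparisons with V0, 623 genes rose and 191 fell. Among the genes that fell in all 3 were 8 of 32 hypoxia genes (VEGFA, HK2, PGK1, ENO2, CA9, BNIP3, PDK1 and LDHA) and 3 of 14 in the LIN28B and let-7 list (LIN28B, HMGA2 and IGF2BP2). Among those that rose in all 3 were 12 of 17 fibroblast markers, 8 of 36 matrix genes and the endothelial genes ESAM, CD34, TEK and TIE1. POSTN, COL3A1, COL1A2, COL1A1, DCN and LUM are counted in both the fibroblast and the matrix list. No expected number was computed for the overlap of all 3.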

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

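All tests of explanations in this part were chosen after the results were seen. The KPC1 effect differed between the runs in 3183 of 15297 genes, with 1739 higher and 1444 lower in run 2 (limma interaction, 3 and 2 libraries per run), and the number was 1300 and 1192 without KPC1 library a or b of run 1 and 1005 and 1028 without KPC1 library a or b of run 2. RNF123 itself differed by 1.53 ± 0.15 on the log2 scale (SE, adjusted p = 0.00032), with more in run 2. The KPC1 effect was higher in run 2 than in run 1 with the largest differences of 11.47 ± 1.02 in IL36RN (adjusted p = 0.00022), 9.92 ± 1.04 in IL36B, 8.59 ± 1.11 in IL1RN and 7.94 ± 1.18 in CCL3. The others among the 10 largest were PNLIPRP3 (7.92), CLDN14 (7.65), BCL11B (7.61), HSD17B2 (7.49), SBSN (7.45) and ANO3 (7.40). The smallest were MAGEC1 (-9.39 ± 0.96, adjusted p = 0.0004), FOXA2 (-8.21), MAGEA6 (-8.15), ZG16B (-7.85), DCC (-7.53), CD96 (-7.24), KRT18 (-7.22), EMB (-7.02), UBE3A-AS1 (-6.88) and SH3RF3 (-6.73). SH3RF3 had an adjusted p of 0.041 and did not pass with limma-voom, without V0 library a or b of run 1, or without any KPC1 library, and MAGEA6 and UBE3A-AS1 remain uncertain because of near-identical and antisense sequence.

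Among the lists, NF-kB targets were higher in run 2 relative to run 1 in 11 and lower in 4 of 26, also adjusted over the list alone (median 1.13, camera adjusted p = 0.020, adjusted p = 0.836 with an estimated correlation), with SOD2 at 2.02 ± 0.37 (adjusted p = 0.0057). Without V0 library c of run 1 that camera adjusted p was 0.0564 and without V0 library b of run 2 it was 0.0652. NF-kB components were higher in 8 and lower in 1 of 26, with 9 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.042, adjusted p = 0.763 with an estimated correlation). The higher ones include RNF123, the gene carried by the KPC1 vector. The call was lost without V0 library a (adjusted p = 0.0817) or c (adjusted p = 0.0564) of run 1 or V0 library b (adjusted p = 0.0613) or c (adjusted p = 0.0844) of run 2. Cell cycle genes were higher in 17 of 36, and in 25 adjusted over the list alone (median 0.55, camera adjusted p = 3.1e-08, adjusted p = 0.752 with an estimated correlation), and RRM2, a ribonucleotide reductase gene, differed by 1.01 ± 0.10 (adjusted p = 0.0004). Cholesterol genes were higher in 12 of 23, and in 16 adjusted over the list alone (median 0.57, camera adjusted p = 1.4e-05, adjusted p = 0.752 with an estimated correlation). Ribosomal protein genes were higher in 10 of 39, and in 13 adjusted over the list alone (median 0.29, camera adjusted p = 8.3e-05, adjusted p = 0.753 with an estimated correlation). Proteasome subunits were higher in 4 of 33, also adjusted over the list alone (median 0.20, camera adjusted p = 0.0098, adjusted p = 0.836 with an estimated correlation). Mitochondrially encoded genes were higher in 11 of 12, and in 12 adjusted over the list alone (median 1.06, camera adjusted p = 3.0e-06, adjusted p = 0.752 with an estimated correlation).

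Matrix genes were lower in run 2 relative to run 1 in 10 of 36, and in 12 adjusted over the list alone (median -0.64, camera adjusted p = 0.00013, adjusted p = 0.752 with an estimated correlation), with CTGF at -1.70 ± 0.28 (adjusted p = 0.0041). Unfolded protein response genes were lower in 10 of 23, also adjusted over the list alone (median -0.36, camera adjusted p = 0.0012, adjusted p = 0.752 with an estimated correlation). Hypoxia genes were lower in 4 and higher in 1 of 32, also adjusted over the list alone (median -0.44, camera adjusted p = 0.048, adjusted p = 0.867 with an estimated correlation). That call was lost without V0 library a (median -0.11, adjusted p = 0.479) or KPC1 library b (adjusted p = 0.0632) of run 1, without V0 library c (median -0.23, adjusted p = 0.220), KPC1 library a (adjusted p = 0.0618) or KPC1 library b (adjusted p = 0.0800) of run 2, and with limma-voom (adjusted p = 0.0542). Fry did not call the run difference for NF-kB targets (adjusted p = 0.170), proteasome (0.182), matrix (0.0659) or hypoxia genes (0.545).

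A set of 42 genes high in V0 of run 2 and near 0 in p50 of run 1 and KPC1 of run 2 took intermediate levels in run 1, and V0 libraries of run 1, all with the same vector, differed 4.78-fold in it, so the expressed protein alone does not account for it. Library b exceeded a by 2.08 on the log2 scale in this set. It fell short in a set of 31 genes with the reverse pattern (-0.91), which excludes depth. Among genes named above, TLR4, E2F7, MAGEC1, MAGEA6, DCC, SH3RF3 and UBE3A-AS1 are in the first set. IL13RA2, SULF1, BCL11B and HSD17B2 are in the second. The changes of all these genes with KPC1, and their run differences, may thus also reflect what differed between tumours with the same vector. Over 22 chromosomes the median ratio of library b to a correlated with that of V0 to KPC1 in run 2 (r = 0.908, permutation adjusted p = 4e-05 from the smallest p that 1e+05 resamples can give). Tumours that hold different shares of cell populations differing in whole chromosomes would give such a correlation. Chromosomes were not compared with other groups of genes, so genes that move alike in both ratios could give it too. The same correlation was 0.687 for library b over c (permutation adjusted p = 0.00092), -0.586 for p50 over V0 (0.006) and -0.314 for KPC1 over V0 in run 1 (0.16). Whether only 2 populations were mixed stays open, since fractions that summed to between 0.459 and 1.12 would decide it only with 1 fixed profile per population, and the genes of a set gave fractions with quartiles up to 0.775 apart in a library.

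Genes raised at least 16-fold with KPC1 in run 1 were 88 in number, with SPINT2 and CD96 among them. Their median effect was 4.73 in run 1 and 0.47 in run 2 (quartiles -0.22 and 1.68), where RNF123 was higher. The level of RNF123 transcripts alone thus does not set them as a group. The run difference could be tested in 43 of them, of which 31 were lower in run 2 and 0 higher. The others did not pass the filter of both runs. The run 1 effect that chose these genes enters this difference, so the choice favoured its direction and the count adds no support. Chosen in 1 KPC1 library of run 1 and measured in the libraries left out, such genes had medians of 3.77 to 5.09 in run 1 and of 0.29 to 1.202 in run 2. Noise of single libraries thus does not account for the difference. The libraries left out were of run 1 too, so selecting genes in that run may still add to it. KRT18 and KRT19 were among the 88 genes, and admixed epithelial cells might have carried them. Of 14 adhesion and splicing markers 2 of 7 tested were higher and 6 (CDH1, ESRP1, RAB25, GRHL2, ELF3 and PRSS8) were listed at 0 in both KPC1 libraries, which argues against such cells but leaves them open, since their profile was not measured.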

How the results depend on the processing

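Asking for at least 2-fold in addition left 1556 genes for KPC1 against V0 in run 1, 2530 for p50 against V0, 1268 for KPC1 against p50, 2847 for KPC1 against V0 in run 2, 1256 over both runs and 1932 for the interaction, and fewer genes follow from the construction. Leaving out 1 library gave 1011 to 5113, 3715 to 8499, 579 to 5937, 1110 to 6781, 1672 to 4088 and 1005 to 3939 genes in the same order, lowest without a KPC1 or p50 library, where fewer libraries remain, and highest without V0 library a of run 1 or run 2, for which the cause was not tested. Fitting only the KPC1 and p50 libraries raised their count from 3463 to 7791, where the wider spread of the single V0 tumours no longer counted, though the cause was not tested. With an estimated correlation camera called 0 lists in each of the 6 comparisons, against 17, 14, 9, 8, 15 and 10 with the preset one, with lowest adjusted p of 0.268, 0.257, 0.324, 0.633, 0.137 and 0.752. Fry called 15, 15, 8, 10, 14 and 6 lists, the last against 10 with camera. For KPC1 against V0 in run 1 fry lost hypoxia (adjusted p = 0.167), NF-kB components (0.714), interferon (0.118) and muscle genes (0.217). For p50 against V0 it lost hypoxia (0.118), muscle (0.131) and mitochondrially encoded genes (0.0814). Between KPC1 and p50 it lost cell cycle (0.149), antigen presentation (0.149), mitochondrially encoded (0.346) and macrophage genes (0.121). In run 2 it lost muscle genes (0.120). The cause was not tested. The correlation of KPC1 and p50 effects in run 1, 0.530, was 0.473 without the filter, 0.611 with a stricter filter on counts per M, 0.466 with a smaller pseudocount and 0.519 to 0.612 without 1 library, and the cause was not tested. With V0 libraries not shared it was 0.358, 0.485 and 0.444 with V0 library a, b or c given to KPC1 and 0.484, 0.418 and 0.397 with that library given to p50, where fewer libraries remain. Upper quartile scaling gave 4270, 7564, 3521, 5415, 3608 and 3163 genes, TMM scaling, chosen after the data were seen, 4300, 7637, 3482, 5510, 3663 and 3192, and limma-voom 4017, 6975, 2775, 5326, 3411 and 2962. Of 498 named gene calls 328 were kept in every alternative. No paired analysis was possible because the packed columns carry no replicate number. The Wald test planned for deposited counts, a block for replicates and the alternatives on mouse genes were not run, and scaling by relative log expression is that of the deposited values. The pools, with 11.9 to 18.0 M reads against 18.4 to 26.8 M in V0, limit what low-count genes can show.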

Other observations

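All tests of explanations in this part, and the keratin and cancer testis lists, were chosen after the data were seen. Hair follicle genes had higher counts with KPC1 in run 2. The tumours grew under mouse skin, and reads of mouse transcripts on human genes could not be told from human reads. Whether these transcripts came from host skin or tumour cells thus cannot be told. KRT25, KRT72 and KRT74, which code for keratins of the inner root sheath of hair, were listed at 0 in every other library and had means of 205, 104.8 and 72.8 normalized counts, though genes at 0 in V0 could only come out higher. KRT71 and TCHH rose by 6.91 ± 0.42 and 6.10 on the log2 scale, and TCHH, present in every group of run 1, also rose with KPC1 there by 1.91 (adjusted p = 0.019). KRT7, KRT8, KRT18 and KRT19 were higher with KPC1 in run 1 by 3.59, 2.67, 4.43 and 6.65, whereas in run 2 KRT19 was higher by 2.66, KRT8 was lower (-1.93) and neither KRT7 (0.24, adjusted p = 0.70) nor KRT18 (-2.79, adjusted p = 0.056) passed. Cancer testis antigens, normally restricted to germ cells, fell in 4 of 5 tested with p50 and in 4 of 5 with KPC1 in run 2 and rose in 2 of 5 with KPC1 in run 1. MAGEC1 had means of 16.7, 427 and 0 in V0, KPC1 and p50 of run 1 and of 391 and 10.4 in V0 and KPC1 of run 2, each run normalized separately.

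KPC1 of run 2 and p50 of run 1, which share no library, moved part of their genes alike. Both were pools set against single V0 tumours, so a part through pooling cannot be told apart. In 1149 genes both were higher and in 736 both lower, against 655 and 480 for independent lists of those sizes, with 608 opposite. Across 15619 genes Pearson r was 0.430 against 0.270 for KPC1 of run 1 and run 2, but Spearman rho was 0.293 against 0.235, and 58.4% against 57.9% had the same sign, so a closer likeness to p50 is not shown. SOD2 stood at 3921 ± 1216 normalized counts in V0 of run 2 and at 3576 ± 20.3 in KPC1 (SD, n = 3 and 2), a level near the 4643 ± 492 of KPC1 in run 1, with runs normalized separately. By chromosome, KPC1 tumours of run 2 had medians above V0 on chromosomes 14 (0.43), 22 (0.44) and 21 (0.32) and below it on chromosome 16 (-0.46). A hypothesis for the genes that moved by run is that tumours grew from different shares of subpopulations of the line. It could be tested by DNA copy number in the same tumours. The r of 0.908 over chromosomes linked 2 tumours with the same vector to the V0 to KPC1 difference of run 2. That r does not test the hypothesis, since it was computed after the pattern was seen and without other groups of genes for comparison.

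Skeletal muscle transcripts varied between tumours with the same vector. The median muscle gene stood at 5.85, 71.5 and 505 normalized counts in the V0 libraries of run 1 and at 298 to 471 in KPC1 and 840 to 884 in p50 libraries, so V0 libraries alone differed 73.9-fold in the median after 1 was added to each value, and the expressed protein alone does not explain the difference. The 11 muscle genes moved together over the 6 V0 libraries (median pairwise r = 0.927, against at most 0.887 in 10000 random lists), and muscle tissue carried with the tumour in varying amounts may be their source. Fibroblast genes did not follow them between V0 tumours. The median log2 ratio per gene of V0 library c to a of run 1 was 0.23 in fibroblast genes and 4.54 in muscle genes. In V0 of run 2 library a had the highest muscle median (215) and the lowest fibroblast median (1595). Fibroblast medians were 3984 and 4315 with KPC1 and 4361 and 4134 with p50, against 1357 to 1644 in V0 of run 1. The V0 values argue against muscle tissue as their source, but no pool entered this comparison, so it is not excluded. Whether the fibroblast transcripts come from host or tumour cells cannot be told without the mouse reads, which were not analysed here.

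The KPC1 difference over both runs was set against other splits of the libraries. Of 100 splits of the 10 libraries into 6 and 4 only 1, the real one, called as many as 3574 genes, and the highest other called 604. These splits moved libraries between runs. Among all 100 splits with 3 and 2 libraries in each run again only the real one called as many. The highest other called 574. The real split is also the only one that separates pools from single tumours. Other splits thus did not give as many calls, but they cannot tell the vector from pooling or from differences between the tumours used. A hypothesis from the genes shared by both runs and p50 is that tumours with either protein were less hypoxic at 21 days, since VEGFA, CA9, PGK1 and LDHA were lower in all 3 comparisons. It was not tested here, and staining of such tumours for hypoxia would test it. The hypoxia list passed camera in all 3 comparisons with a preset correlation and in 0 with an estimated correlation, and fry kept it in run 2 (adjusted p = 0.0215) but not for KPC1 (0.167) or p50 (0.118) in run 1.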
